A study of Mus musculus with 2 samples.

How the data were processed

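Single-cell 5' RNA libraries (10x Chromium) were made from cells of MC38 tumours, 1 library of cells pooled from 4 mice for each of the groups DFMO and water. The sources name Cell Ranger 3.02, Scanpy 1.4.4 and the genome build mm10. The authors deposited 1 matrix of raw UMI counts for 10720 cells and 17775 genes, with a table of cells that gives each cell's group. Sums of the deposited counts per cell equalled the UMI totals in the cell table. The authors' table of genes holds total counts and a signal column, the mean UMIs per gene, over 13496 cells, more than the matrix has, and the gene table was therefore not used for values. The matrix holds 0 mitochondrially encoded genes and 0 ribosomal protein genes. The authors' number of genes per cell exceeded the genes detected in the matrix by 40 to 212. It reached at most 5997 in DFMO and 5984 in water, and the limits used on cells before deposit are not given in the sources used here. Coordinates came from GENCODE M21 on mm10 by Ensembl gene identifier and matched 17760 genes.

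Cells with at least 200 genes were kept, which removed 1 water cell. Doublets were called by Scrublet in scanpy 1.11.5, per library with an assumed rate of 0.05, and 53 DFMO cells (1.19%) and 120 water cells (1.92%) were removed. Only 26.7% (DFMO) and 36.9% (water) of simulated doublets lay above the thresholds, so doublets may remain among the kept cells. The planned limit on mitochondrial UMIs had nothing to act on. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes without immunoglobulin and T cell receptor segments, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 0) gave 29 clusters, without batch correction. Marker sets, gene lists, comparisons, the rule for naming genes and the alternatives were chosen before the data were examined, apart from those described as added. The rule that turned markers into class names was set after the clusters were seen. A marker counted when it was at least 2 times as high in the cluster as elsewhere and seen in at least 0.1 of its cells, and a class also needed a marker among the cluster's 10 leading genes. Clusters without a name and under 20 CPM of Ptprc were called Ptprc-low. No cluster passed the rule for tumour epithelium, neutrophils, mast cells, plasma cells or erythroid cells. Markers of gamma-delta T cells, innate lymphoid cells, nonclassical monocytes, basophils and platelets were scored, but the rule gave them no class of their own.

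UMIs were summed per library and class. CPM were taken over all genes of the sum, with exact Poisson 95% intervals, and the log2 ratio of DFMO over water had an exact conditional binomial 95% interval. Shares of cells had exact Clopper-Pearson 95% intervals. All of these cover counting error only. Each group was 1 library, so no p-value, standard error or count of changed genes was made, and cells were not used as replicates. No paired analysis was possible because each group had 1 library. Ratios were described in classes with at least 100 kept cells in each library, in all kept cells and in Ptprc-low cells. A list was summarised by the median over members with at least 30 UMIs, and set among the medians of 10000 random lists matched on mean CPM in 20 bins. A list is called inside its random range when it lay in the central 95% of these. Members with 0 UMIs in 1 library were left out of medians. Single genes were named from the 10 highest and 10 lowest ratios among genes with at least 100 UMIs in the class and at least 50 CPM in 1 library, without receptor segments. For the other T cell-like class, a mixture of clusters, this table was made but is not described. Of the urea cycle and polyamine lists, the members named had an interval that excluded 0, with Odc1, Arg1 and Ass1 in any case.

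The lists covered 18 groups of genes. The carry-over list holds genes of erythrocytes, fibroblasts, endothelium and tumour epithelium. Lists of lymph node stroma and of Y-linked genes were added for tests in the closing section, and the reads' ambiguity was gauged by the share of each gene's 31-mers found in transcripts of other genes. The alternatives were doublets kept, at least 500 genes per cell, Leiden resolutions 0.5 and 2.0, TMM library sizes (edgeR 4.0.16 in R 4.3.3), totals without receptor segments, a mean over cells, members with at least 10 or 100 UMIs, a ratio of summed UMIs and thinning to 1000 UMIs per cell. Values of the CD8 T cell-like class without cluster 8, of clusters 6, 7, 9 and 10 alone and of the fibroblast-like class without subcluster 20 of resolution 2.0 were added after seeing the data. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

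The intervals and percentiles were tested on simulated Poisson counts with the library totals and the gene means over both libraries of 3 of the comparisons, in which 200 genes were changed by 1.5, 2.0 or 4.0 times. In the CD8 T cell-like simulation (9105 genes) 96.1% of the intervals held the true ratio, and the interval excluded 0 on the right side for 89.6% of genes changed 1.5 times and 100.0% of those changed 2.0 times. In the monocyte and macrophage-like simulation (8505 genes) 96.3% of intervals held it, with 71.6% and 93.5% recovered, and in the fibroblast-like simulation (10734 genes) 96.0%, with 76.1% and 93.5%. Of 100 lists of 20 unchanged genes, 93.0%, 94.0% and 94.0% lay in the central 95%, and all 20 lists of raised genes lay above it in each. The simulated genes were independent Poisson draws, so this checked the calculation only. It did not cover UMIs concentrated in a few cells or list members that vary together, for which intervals and random ranges can be too narrow.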

Results

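The question was how DFMO, an inhibitor of ornithine decarboxylase, the enzyme that makes the polyamine putrescine from ornithine, changed the expression of urea cycle genes in cells from mouse tumours. MC38, a mouse colon carcinoma line, was implanted in C57BL/6 mice. From day 7 the mice received DFMO or water by gavage for 14 days. Tumours were dissociated, and a Ficoll step was used to obtain immune cells. Cells of 4 mice per group were pooled and sequenced as 1 single-cell 5' library per group. The DFMO library held 23588037 deposited UMIs (unique molecular identifiers), and the water library held 59748244. After filtering, 4419 DFMO and 6127 water cells were kept, with a median of 2208 and 6316 UMIs and of 1198 and 2273 genes per cell. With 1 library per group there were no replicates, so no spread between animals could be measured. All intervals are 95% intervals of counting error only, and no difference between the libraries was tested against replicate error.

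The libraries differed in which cells they held. B cell-like cells were 34.4% of the kept DFMO cells (33.0 to 35.8, exact binomial) and 1.03% of the water cells (0.791 to 1.31). CD4 T cell-like cells were 14.4% (13.4 to 15.5) and 0.669% (0.481 to 0.907). Monocyte and macrophage-like cells were 3.58% (3.05 to 4.17) in DFMO and 17.3% (16.4 to 18.3) in water. Fibroblast-like cells were 2.83% (2.36 to 3.36) and 15.5% (14.6 to 16.4), and clusters low in Ptprc, the gene of the leukocyte antigen CD45, were 12.3% (11.4 to 13.3) and 31.9% (30.7 to 33.1). CD8 T cell-like cells were 17.7% (16.6 to 18.9) and 12.9% (12.0 to 13.7), NK cell-like cells 4.64% (4.04 to 5.30) and 5.78% (5.21 to 6.39), and regulatory T cell-like cells 1.77% (1.4 to 2.2) and 2.94% (2.53 to 3.39). At the coarser Leiden resolution of 0.5 the regulatory T cell-like class was 4.12% of DFMO and 3.15% of water, so its direction depended on the clustering. The immune cells were enriched before sequencing and the depositors removed cells by limits that are not given in the sources used here. These shares therefore describe the deposited cells and not the tumours.

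**Figure D1:**
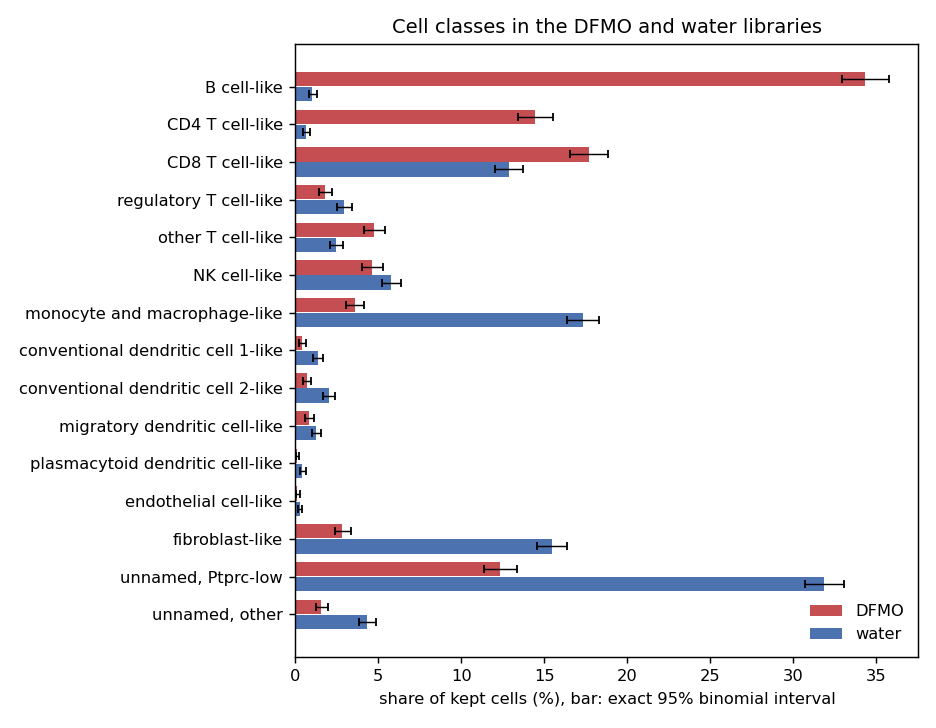
Share of kept cells (%, x axis) in each cell class (y axis) in the DFMO (red) and water (blue) libraries, with exact 95% binomial intervals as error bars. B cell-like cells reach 34.4% in DFMO against 1.03% in water, while monocyte and macrophage-like, fibroblast-like and Ptprc-low cells are larger shares of the water library.

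Within T and NK cell-like cells, CD4 T cell-like cells were 33.4% (31.3 to 35.5) in DFMO and 2.71% (1.95 to 3.65) in water. NK cell-like cells were 10.7% (9.37 to 12.2) and 23.4% (21.3 to 25.6), and regulatory T cell-like cells 4.08% (3.24 to 5.07) and 11.9% (10.3 to 13.6). The CD4 T cell-like class was 1 cluster (cluster 4) whose leading genes, Lef1, Tcf7, Dapl1, Il7r and S1pr1, are genes of naive and recirculating T cells. The CD8 T cell-like class joined clusters of different kinds. Cluster 8, led by Dapl1, Lef1 and Tcf7, held 444 DFMO and 42 water cells. Cluster 7, led by the granzyme gene Gzmf and the checkpoint genes Pdcd1 and Lag3, held 215 DFMO and 370 water cells. Cluster 18 of the other T cell-like class, led by Izumo1r, Foxp3 and Cd4, held 116 DFMO and 17 water cells. It was 6.07% (5.04 to 7.23) of T and NK cell-like cells in DFMO and 1.12% (0.655 to 1.79) in water. It met 5 of 6 regulatory T cell markers. At Leiden resolution 0.5 the regulatory T cell-like class held 182 DFMO and 193 water cells. The size of the difference in regulatory T cell-like share given above therefore depended on the clustering and naming. B cell-like cluster 26, led by Mef2b and Rgs13, genes of germinal centre B cells, held 25 DFMO and 0 water cells. Among named leukocytes without B cell-like cells and clusters 4 and 8, a set chosen after seeing the data, NK cell-like cells were 19.1% (16.8 to 21.5) in DFMO and 12.6% (11.4 to 13.9) in water. In that set the NK cell-like share was the higher one in DFMO, while monocyte and macrophage-like cells stayed lower in DFMO at 14.7% (12.6 to 17.0) against 37.9% (36.1 to 39.7). Among the named myeloid classes, which leave out the unnamed cluster 15, monocyte and macrophage-like cells were 64.5% (58.1 to 70.5) in DFMO and 77.5% (75.2 to 79.7) in water, and migratory dendritic cell-like cells 14.3% (10.2 to 19.3) and 5.55% (4.40 to 6.90).

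The urea cycle and polyamine genes were carried by different cell classes in both libraries. Odc1, the ornithine decarboxylase gene (ENSMUSG00000011179, mm10 chromosome 12, 17544794 to 17551505), was highest in regulatory T cell-like cells in both libraries. It stood at 1140 CPM (UMIs scaled to the UMI total of the class; exact Poisson interval 1032 to 1256) in DFMO and 1323 CPM (1235 to 1416) in water. Odc1 was 162 CPM (139 to 187) and 160 CPM (142 to 179) in NK cell-like cells, 152 CPM (138 to 168) and 165 CPM (150 to 180) in CD8 T cell-like cells, and 50.2 CPM (36.8 to 67.0) and 36.6 CPM (31.4 to 42.5) in monocyte and macrophage-like cells. UMIs of Odc1 were seen in 71.8% of DFMO and 76.1% of water regulatory T cell-like cells, at medians of 3448.5 and 2624.5 UMIs per cell. After thinning every cell to 1000 UMIs these shares were 46.8% and 55.0%. In B cell-like cells of the DFMO library, at a median of 1773 UMIs, they were 14.1% before and 7.15% after thinning.

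Arg1, the arginase gene that turns arginine into ornithine and urea (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), was a myeloid gene in these cells. In monocyte and macrophage-like cells it stood at 224 CPM (194 to 257) in DFMO and 202 CPM (190 to 215) in water, with a UMI in 15.8% and 11.2% of cells at medians of 5642.5 and 4253 UMIs. In B cell-like cells, taken as background, it stood at 0.32 CPM (0.01 to 1.79) in DFMO, with a UMI in 0.07% of cells at a median of 1773 UMIs. Background was higher in some water classes. Arg1 was 9.33 CPM (5.53 to 14.75) in NK cell-like and 14.77 CPM (6.75 to 28.03) in other T cell-like water cells. Those UMIs came from 2 cells in each class. The highest Arg1 level was in cluster 15, a small myeloid cluster led by Mmp12 and Arg1 that fell outside the naming rule, with 1163 CPM (1010 to 1334) in 31 DFMO cells and 2197 CPM (2097 to 2301) in 156 water cells. Ass1, the argininosuccinate synthase gene that rebuilds arginine from citrulline (ENSMUSG00000076441, chromosome 2, 31470207 to 31520672), was 694 CPM (610 to 785) and 657 CPM (595 to 723) in regulatory T cell-like cells. It was 460 CPM (421 to 501) and 353 CPM (216 to 546) in CD4 T cell-like cells, 335 CPM (299 to 375) and 341 CPM (325 to 358) in monocyte and macrophage-like cells, and 5.19 CPM (1.90 to 11.3) and 3.63 CPM (1.46 to 7.48) in NK cell-like cells.

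**Figure D2:**
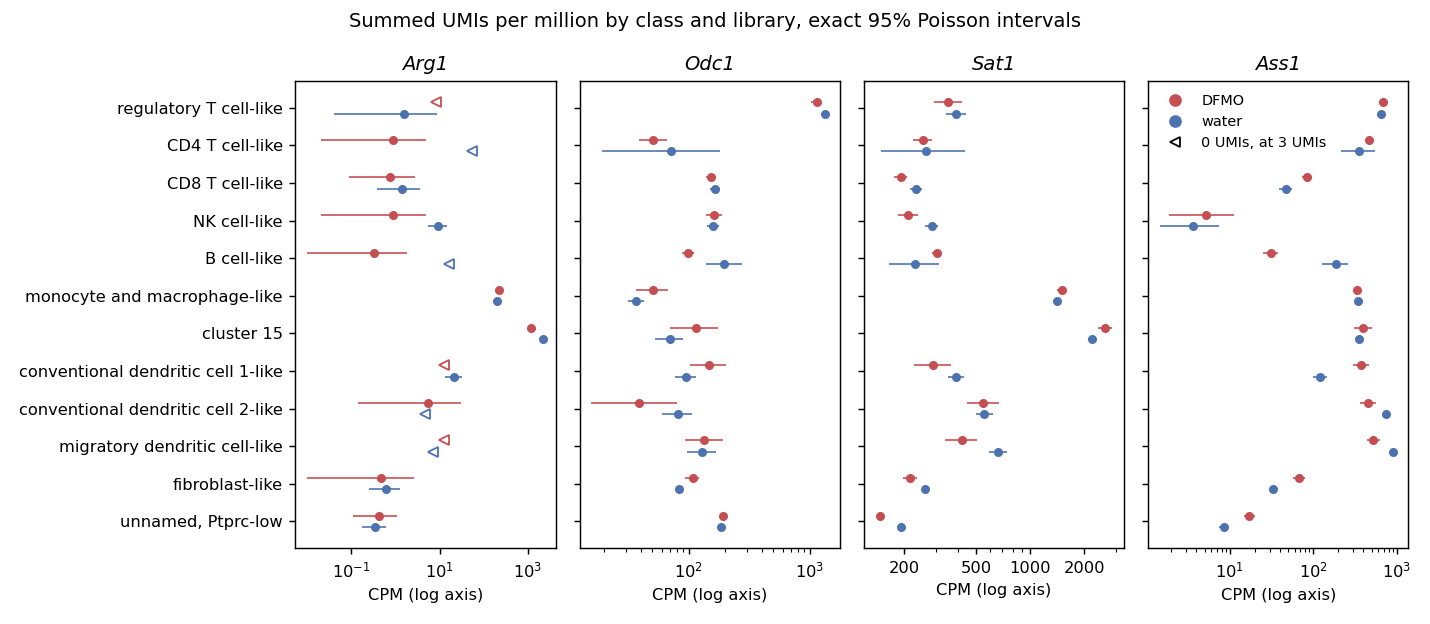
UMIs scaled to the total of the class (CPM, x axes, logarithmic) of Arg1, Odc1, Sat1 and Ass1 in each cell class (y axis) in DFMO (red) and water (blue), with exact 95% Poisson intervals as bars and open triangles at 3 UMIs for classes with 0 UMIs. Arg1 is highest in cluster 15 (1163 and 2197 CPM) and Odc1 in regulatory T cell-like cells (1140 and 1323 CPM).

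Set against water, the urea cycle genes as a group stood near their random range in the leukocyte classes and above it in the fibroblast-like class. Over all kept cells the median log2 ratio of DFMO over water was 0.02 (9 members higher, 8 lower) for the urea cycle and arginine list and -0.08 (10 higher, 11 lower) for the polyamine list. These medians lay at percentiles 37.6 and 24.8 of 10000 random lists of like size and expression. That balance depended on the weighting: with each cell weighted alike, so that cells with many UMIs count no more than others, an alternative for lists added after seeing the data, the urea cycle list stood at -0.59 (6 higher, 11 lower; percentile 1.06) and the polyamine list at -0.25 (9 higher, 12 lower; percentile 17.5). Among all kept cells Arg1 was lower in DFMO, with a log2 ratio of -1.27 (-1.41 to -1.13). Cluster 15 held 205 DFMO and 1800 water UMIs of Arg1, where all deposited cells, removed ones included, held 3382. Within cluster 15 Arg1 was also lower in DFMO, at 1163 CPM (1010 to 1334) against 2197 CPM (2097 to 2301) in water. In monocyte and macrophage-like cells it stood at 224 CPM in DFMO and 202 CPM in water. Cluster 15 was 0.702% (0.477 to 0.994) of DFMO and 2.55% (2.17 to 2.97) of water cells. The share of monocyte and macrophage-like cells was also lower in DFMO. Ass1 (0.51), Glul (0.39), Slc25a15 (0.36) and Glud1 (0.13) were higher with intervals above 0, and Asl (-0.23), Slc25a13 (-0.29), Gatm (-0.37) and Pycr1 (-0.37) were lower. With each cell weighted alike several of these stood further from 0 or nearer to it: Arg1 at -2.28, Gatm at -1.50, Pycr1 at -1.41, Slc25a13 at -1.06 and Asl at -0.59, and Ass1 at 0.19 and Glud1 at 0.03. Of members whose interval held 0, Nos2 went from 0.07 to -1.13, Slc7a2 from -0.045 to -1.67, Prodh from -0.14 to -0.94, Slc7a1 from 0.13 to -0.21 and Aldh18a1 from 0.02 to -0.19, and Oat stood at 0.27. Odc1 itself stood at 0.05 (-0.01 to 0.10), and at -0.26 with each cell weighted alike. Sms, the spermine synthase gene, was higher at 0.73 (0.65 to 0.81), as were Paox (0.46), Dohh (0.35), Amd1 (0.29), Atp13a2 (0.26), Atp13a3 (0.23), Dhps (0.13), Azin1 (0.11) and Oaz1 (0.07). Under that weighting Azin1 turned to -0.10, Dohh stood at 0.14, Atp13a3 at 0.02, Dhps at 0.48, Oaz1 at 0.21 and Sms at 0.84. Sat2 (-0.93), Oaz2 (-0.57), Smox (-0.49), Azin2 (-0.47), Srm (-0.42), Sat1 (-0.37), Mtap (-0.25), Eif5a (-0.16) and Slc3a2 (-0.16) were lower. Weighted in that way, Sat2 stood at -2.40, Azin2 at -1.42, Smox at -1.32, Sat1 at -0.70, Srm at -0.64, Mtap at -0.54, Slc3a2 at -0.46 and Eif5a at -0.27.

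Within classes, Sat1, whose enzyme acetylates spermidine and spermine for their breakdown or export (ENSMUSG00000025283, chromosome X, 155213132 to 155216449), was lower in DFMO in 4 sets. Its log2 ratio was -0.44 (-0.67 to -0.22) in NK cell-like, -0.29 (-0.46 to -0.12) in CD8 T cell-like, -0.28 (-0.42 to -0.13) in fibroblast-like and -0.39 (-0.48 to -0.31) in Ptprc-low cells. In monocyte and macrophage-like cells Sat1 stood at 0.09 (0.00 to 0.17), and at -0.00043 with library sizes scaled by the trimmed mean of M values (TMM). Odc1 stood at -0.11 (-0.31 to 0.08) in CD8 T cell-like, 0.02 (-0.25 to 0.29) in NK cell-like, 0.46 (-0.05 to 0.93) in monocyte and macrophage-like, 0.37 (0.15 to 0.58) in fibroblast-like and 0.04 (-0.04 to 0.12) in Ptprc-low cells. In CD8 T cell-like cells without cluster 8 it was higher in DFMO, at 0.37 (0.17 to 0.58), as were Smox (0.62; 0.01 to 1.23), Sms (0.26; 0.02 to 0.49) and Oaz1 (0.17; 0.10 to 0.23). Asl (-0.67; -1.25 to -0.11), Srm (-0.56; -0.89 to -0.23), Mtap (-0.54; -0.95 to -0.15), Sat1 (-0.29; -0.49 to -0.10) and Eif5a (-0.21; -0.29 to -0.13) were lower there. In cluster 7 alone Odc1 (0.49), Sms (0.41) and Oaz1 (0.21) were also higher, and Mtap (-0.54), Srm (-0.44), Sat1 (-0.34) and Eif5a (-0.22) lower, with intervals that excluded 0. Ass1 was higher in the whole CD8 T cell-like class at 0.84 (0.52 to 1.16), but stood at -0.30 (-0.77 to 0.16) without cluster 8 and at -0.57 in cluster 7 alone. Both of these alternatives were added after seeing the data.

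In the fibroblast-like class the urea cycle list was higher in DFMO, with a median log2 ratio of 0.34 (13 of 14 measured members higher; percentile 100). The class was named by markers alone. Its Y-linked genes, described in the closing section, stood at 1.87 CPM (1.21 to 2.76) over both libraries, against 148 CPM in named leukocytes. Most of its cells may therefore be of the implanted line and not host fibroblasts. In this class Nos2, the inducible nitric oxide synthase gene, stood at 0.97 (0.67 to 1.25) and Ass1 at 1.04 (0.75 to 1.32). Slc7a1 (0.53), which carries cationic amino acids, Aldh18a1 (0.38), Gatm (0.34), Oat (0.34) and Glud1 (0.33) had intervals above 0, although Gatm turned to -0.14 among cells with at least 500 genes. In Ptprc-low cells the same list had a median of 0.17 (12 of 14 higher; percentile 96.6), with Ass1 at 1.02 (0.73 to 1.30), Nos2 at 0.62 (0.45 to 0.79), Slc25a15 at 0.47, Slc7a1 at 0.41, Aldh18a1 at 0.17 and Gatm at 0.17. The polyamine list had a median of 0.10 (12 of 19 higher; percentile 89.5) in fibroblast-like and 0.05 (12 of 20 higher; percentile 80.3) in Ptprc-low cells. Its members with intervals above 0 in both were Amd1 (0.57 and 0.37), Atp13a3 (0.60 and 0.41), Dohh (0.54 and 0.47) and Mtap (0.27 and 0.08), and Oaz2 was lower in both (-0.35 and -0.37). Eif5a stood at 0.10 and -0.09 and Atp13a2 at -0.74 and 0.42, so both differed in direction between these sets. Enoph1 (0.45) was higher in fibroblast-like cells. In Ptprc-low cells Sms (0.27), Azin1 (0.25) and Slc3a2 (0.07) were higher and Srm (-0.20) lower.

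In the leukocyte classes both lists had medians inside their random ranges. One single cluster differed: in cluster 6 of the monocyte and macrophage-like class, added after seeing the data, the urea cycle list stood at 0.41 (7 of 9 higher, percentile 98.9). That lay above its random range (-0.231 to 0.353), while cluster 10 (0.10) lay inside its own. The urea cycle list stood at 0.14 in CD8 T cell-like (6 of 9 higher), 0.02 in NK cell-like (5 of 9 higher) and 0.11 in monocyte and macrophage-like cells (7 of 11 higher). The polyamine list stood at -0.01 (9 of 18 higher), 0.07 (11 of 16 higher) and 0.19 (13 of 18 higher). In CD8 T cell-like cells Atp13a2 (0.82), Amd1 (0.65), Glul (0.63), Aldh18a1 (0.58), Oat (0.43) and Oaz1 (0.18) were higher. Asl was lower there at -0.62, and Eif5a stood at -0.17, but at 0.00237 with each cell weighted alike. These whole-class ratios include the cluster led by Dapl1, Lef1 and Tcf7, with 444 DFMO and 42 water cells. Of the genes higher in the class, only Oaz1 was among those named above as higher without that cluster. A different mix of clusters was not separated from the ratios of the others. Asl and Eif5a were lower without it too. In NK cell-like cells Dohh (1.35), Glul (0.82), Azin1 (0.51), Glud1 (0.31) and Oaz1 (0.13) were higher. In monocyte and macrophage-like cells Sms (1.0), Arg2 (0.94), Glud1 (0.37), Glul (0.34), Oaz1 (0.24) and Eif5a (0.14) were higher, and Arg1 stood at 0.15 (-0.08 to 0.37). Arg1 depended on which cells were named and how they were weighted. With doublets kept it was -0.39, because a cluster holding all 187 cells of the Arg1-rich cluster 15 then met the naming rule and joined the class; without that cluster it was 0.18. It was -0.15 with each cell weighted alike. Dohh had 46.2% of its 31-mers in transcripts of other genes, which limits what its UMIs show.

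In the sum of all kept cells Fcer2a, the low-affinity IgE receptor gene, had the highest log2 ratio, 6.68 (6.35 to 7.02). It was followed by Fcmr (6.59), Ms4a1 (6.24) and Cd79a (5.98), a part of the B cell receptor complex, and then by Blk, Bank1, Tnfrsf13c, Cd79b and Gm30211 down to 4.89. The lowest ratios belonged to Ftl1-ps1 (-1.92), Col1a1 (-1.86), a collagen chain, Apoe (-1.78) and the chemokine gene Ccl7 (-1.63). Cebpd, Ccl12, Postn, Ms4a7, C1qa and Gas1 followed, up to -1.40. The order differed with each cell weighted alike: Fcmr (5.52) stood above Fcer2a (5.39), and Col1a1 (-3.41), Postn (-2.82) and Apoe (-2.65) below Ftl1-ps1 (-2.43). The shares of B cell-like, fibroblast-like and macrophage-like cells differed in the same directions. For the T cell lists in this sum, effector molecules had a median of 0.65 (19 of 19 higher), exhaustion and checkpoint genes 0.70 (13 of 13), naive and memory genes 3.14 (12 of 12) and regulatory T cell genes 0.69 (10 of 10), beside a share of T cell-like cells of 38.6% in DFMO and 18.9% in water. As a ratio of summed UMIs the naive and memory list stood at 1.64. Weighting each cell alike, only this list stayed higher, at 2.84 (12 of 12), while effector molecules turned to -0.41 (16 of 19 lower), exhaustion and checkpoint genes to -0.29 (12 of 13 lower) and regulatory T cell genes to -0.10 (8 of 10 lower), so their direction in this sum was not settled.

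Type I interferon response genes were lower in DFMO in the leukocyte classes. In CD8 T cell-like cells the list's median log2 ratio was -0.72 (17 of 18 members lower; percentile 0.0), with Ifit2 (-1.02) and Rsad2 (-0.93) lowest. Without cluster 8 it was -0.51 (17 of 18 lower) and in cluster 7 alone -0.39 (14 of 16 lower). In cluster 11 of this class it was -0.09 (10 of 18 lower; percentile 28.4), inside its random range. In NK cell-like cells the median was -0.50 (17 of 18 lower; percentile 0.0), with Oasl2 (-1.70) and Ifi27l2a (-1.66) lowest. In monocyte and macrophage-like cells it was -0.47 (18 of 19 lower; percentile 0.0), with Oas1a (0.08) highest and Ifi44 (-1.96) and Ifit3b (-1.15) lowest. Of the clusters of this class, cluster 6 stood at -0.44 and cluster 10 at 0.05. In Ptprc-low cells the same list was higher in DFMO, with a median of 0.29 (16 of 19 higher; percentile 100), Cmpk2 (0.99) and Rsad2 (0.83) being highest and Ifit2 (-0.20) and Ifit1 (-0.04) lowest. Cluster 5 carried this, at 0.51 (percentile 100), while the Ptprc-low clusters 2 (0.16), 3 (0.07) and 12 (0.03) lay inside their random ranges. In fibroblast-like cells it stood at 0.09 (12 of 19 higher; percentile 94.9), but at -0.10 as a ratio of summed UMIs. The macrophage gene Apoe was also lower in DFMO in NK cell-like cells, at 0.86 CPM (0.02 to 4.82) against 11.9 CPM (7.56 to 17.9) in water. In CD8 T cell-like cells it stood at 2.24 against 16.1 CPM. Carry-over from macrophages was not separated from the interferon medians of these 2 classes. The difference between classes was not tested, as there was 1 library per group.

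In CD8 T cell-like cells the highest ratios belonged to Igfbp4 (4.21; 3.67 to 4.82), Dapl1 (3.52), Nsg2 (3.30), Rflnb (3.21), Tmem108 (3.14), Tdrp (2.93), Tcf7 (2.82), Ripor2 (2.79) and Lef1 (2.74). Most cells of cluster 8, which Dapl1, Lef1, Nsg2 and Tcf7 lead, were DFMO cells, and without that cluster Nsg2 (-0.55), Tmem108 (-0.51), Tdrp (-0.13), Tcf7 (-0.04) and Lef1 (-0.04) turned below 0. The lowest ratios belonged to the chemokine genes Ccl1 (-3.59; -4.11 to -3.10) and Xcl1 (-2.40; -2.56 to -2.23), to Csf2 (-2.12), which encodes the cytokine GM-CSF, and to Penk (-1.94), Fcer1g (-1.84) and Gzma (-1.59). Slc16a11 (-1.46), Cdkn1a (-1.31), Spp1 (-1.29) and Ccr8 (-1.25) followed. Without cluster 8 Ccl1 stood at -2.93 (-3.45 to -2.45) and Xcl1 at -2.02 (-2.20 to -1.84), and in cluster 7 at -3.73 and -2.16. Few cells carried most of some of these UMIs: 1 water cell held 35.1% of the Ccl1 UMIs, and Penk was seen in 5 DFMO and 16 water cells. Gzma turned to 1.21 in cluster 7, where the chemokine genes Ccl4 (0.74) and Ccl3 (0.74) were also higher in DFMO. Among cells with at least 500 genes Ccl1 stood at -2.95, Csf2 at -1.46 and Penk at -1.0.

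The T cell lists in the CD8 T cell-like class depended on cluster 8. Naive and memory genes had a median log2 ratio of 2.61 (12 of 12 higher), with Dapl1 highest and Bach2 (1.37) and Satb1 (1.68) lowest, and 0.41 (10 of 12 higher) without cluster 8. Effector molecules had a median of -0.50 (17 of 19 lower), with Eomes (0.91) and Gzmf (0.91) highest and Xcl1 and Gzma lowest. Without cluster 8 the effector median was 0.13 (12 of 18 higher), and in cluster 7 it was 0.24. Exhaustion and checkpoint genes stood at -0.32 (11 of 13 lower), with Ctla4 (0.04) and Tox (0.02) highest and Tnfrsf9 (-0.80) and Tnfrsf18 (-0.65) lowest, and at 0.34 (10 of 13 higher) without cluster 8 and 0.16 in cluster 7. Regulatory T cell genes stood at -0.51 (6 of 8 lower) and at -0.01 without cluster 8. The cell cycle list, from Tubb5 (0.13) and Cenpe (-0.08) to Tyms (-1.15) and Rrm2 (-0.90), had a median of -0.49 (23 of 24 lower), 0.0 without cluster 8 and -0.26 in cluster 7. Glycolysis and hypoxia genes had -0.38 (18 of 21 lower), from Pdk1 (1.25) and Gapdh (0.20) to Bnip3 (-0.84) and Hk2 (-0.72), and -0.04 without cluster 8.

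Other lists in CD8 T cell-like cells were as follows. Amino acid stress genes, the targets of the transcription factor ATF4, had a median log2 ratio of -0.36 (10 of 13 lower), from Shmt2 (0.52) and Phgdh (0.10) to Atf3 (-1.22) and Nupr1 (-0.80), and -0.24 (10 of 12 lower) without cluster 8. MYC targets and ribosome biogenesis genes stood at -0.05 (12 of 20 lower), at 0.25 (16 of 20 higher; percentile 99.6) with each cell weighted alike, and without cluster 8 at -0.29 (16 of 20 lower; percentile 0.0), with Odc1 (0.37) and Mybbp1a (0.29) highest and Nop16 (-0.72) and Hspe1 (-0.56) lowest. Interferon gamma response and antigen presentation genes stood at -0.07 (11 of 21 lower), mitochondrial respiration genes at 0.00 (12 of 24 lower) and immediate early stress genes at 0.05 (8 of 18 lower), all inside their random ranges. The carry-over list of genes of other tissue cells had a median of -0.84 over 5 measured members. The macrophage gene Apoe stood at 2.24 CPM (0.82 to 4.87) in DFMO and 16.1 CPM (11.8 to 21.6) in water in these T cells, and the B cell gene Cd79a at 8.21 CPM (5.15 to 12.4) and 0.36 CPM (0.01 to 1.99).

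In NK cell-like cells the lowest ratios included interferon-induced and dividing-cell genes. These were Gzmf (-3.75; -4.72 to -2.92), Ccl1 (-2.72), Pimreg (-1.70), Ifi27l2a (-1.66), Ube2c (-1.46), which acts in mitotic exit, Gclm (-1.40), Fzr1 (-1.25), Atf3 (-1.18), Gm10282 (-1.14) and Ifitm3 (-1.11). The cell cycle list had a median of -0.38 (23 of 24 lower; percentile 0.0), from Mcm6 (0.03) and Mcm2 (-0.15) to Ube2c and Cdk1 (-1.08). The class joined cluster 9, with 184 DFMO and 286 water cells, and the deeper cluster 23, with 21 and 68. In cluster 9 alone, added after seeing the data, the median was -0.46 (15 of 16 lower). Several of the highest ratios rested on few cells: 1 DFMO cell held 1185 of the 1194 UMIs of Gzmg (3.27), another 81.3% of those of Gzme (1.21) and another 79.2% of those of Mt2 (1.29). With each cell weighted alike Gzme stood at -0.10 and Mt2 at -0.14. Cd74 (2.12), H2-Aa (2.02) and H2-Eb1 (1.17), genes of MHC class II antigen presentation, were higher, as were Ifitm1 (1.81), Ifna2 (1.72), Ccl3 (1.60) and 1810009A15Rik (1.30). Ifna2 depended on the processing, at 0.40 among cells with at least 500 genes and 2.68 with each cell weighted alike, and Ccl3 stood at 0.87 under that weighting. Cd74 was seen in 28 of 205 DFMO cells, and the B cell gene Cd79a stood at 45.0 CPM (33.6 to 59.0) in DFMO against 2.07 CPM (0.56 to 5.31) in water in the same class. The 52 DFMO UMIs of Cd79a came from 8 cells, so doublets that were not called were not separated from these ratios.

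The naive and memory list in NK cell-like cells had a median of 0.49 (8 of 8 higher; percentile 99.9), with Ccr7 (1.67) highest and Id3 (0.10) and Klf2 (0.22) lowest. Neither carry-over of transcripts from other cells nor doublets that were not called were separated from this, as Cd79a was higher in the same class (45.0 against 2.07 CPM). Effector molecules stood at 0.11 (12 of 18 higher; percentile 97.3), from Ccl3 and Ccl5 (0.71) to Gzmf and Gzmc (-0.37). Amino acid stress genes stood at -0.16 (7 of 11 lower), immediate early stress genes at 0.11 (12 of 18 higher), exhaustion and checkpoint genes at -0.06 (8 of 12 lower) and regulatory T cell genes at -0.03 (3 of 5 lower). Interferon gamma genes (0.01), glycolysis genes (0.01), MYC targets (0.01) and respiration genes (-0.03) lay near 0. All of these but the naive and memory list were inside their random ranges. In cluster 9 alone the amino acid stress list stood at -0.31 (9 of 11 lower; percentile 0.14), below its range (-0.202 to 0.261). The other lists that were inside in the whole class stayed inside in cluster 9.

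In monocyte and macrophage-like cells the neutrophil and suppressor myeloid list was higher in DFMO. Its median was 0.66 (9 of 11 higher; percentile 100), with Retnlg (1.69) and S100a8 (1.12) highest and Il1r2 (-1.28) and Trem1 (-0.46) lowest, though S100a8 was seen in 9 DFMO and 49 water cells, and stood at 0.38 among cells with at least 500 genes and 0.41 with doublets kept. The B cell gene Cd79a stood at 50.2 CPM (36.8 to 67.0) in DFMO, in 4 cells, and 7.2 CPM (4.99 to 10.1) in water, in 5 cells, of this class. The highest single ratios were those of Bcl6 (1.46; 0.92 to 1.99), Rnasek (1.27), S100a8, Adgre4 (1.12), Tec (1.08), Rpia (1.08), Dynlt1b (1.04), Serpinb2 (1.02), S100a4 (1.02) and Rnaset2b (1.01). The lowest after Hbb-bs (-5.63), a haemoglobin gene of which 1 water cell held 78.6% of the UMIs, was Ifnb1 (-1.94; -2.71 to -1.25), the interferon beta gene. It was followed by Ftl1-ps1 (-1.82), Ube2c (-1.45), Hspa1b (-1.43), Spp1 (-1.33), Prtn3 (-1.31), Pf4 (-1.29), Tmem119 (-1.27) and Ifit3b (-1.15). With doublets kept Hspa1b stood at -0.07 and Ifit3b at -0.34, and at -1.44 and -1.15 when the cluster that then joined the class was left out. The alternative and tumour-associated macrophage list stood at -0.13 (9 of 17 lower; percentile 2.6), from Gpnmb (2.46) and Chil3 (0.67) to Mmp12 (-4.06) and Spp1, and the inflammatory macrophage list at -0.09 (7 of 12 lower; percentile 11.8).

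The cell cycle list in this class had a median of -0.21 (15 of 22 lower; percentile 0.7), from Top2a (0.75) and Mcm6 (0.60) to Cdc20 (-2.84) and Ccnb2 (-2.42). Amino acid stress genes had -0.23 (11 of 15 lower; percentile 1.0), from Slc7a5 (0.99) and Phgdh (0.89) to Sesn2 (-3.06) and Ddit3 (-0.60). Interferon gamma genes stood at -0.08 (14 of 25 lower), respiration genes at 0.07 (16 of 24 higher), glycolysis genes at 0.06 (14 of 22 higher), MYC targets at 0.10 (13 of 19 higher) and immediate early stress genes at 0.08 (11 of 18 higher), inside their random ranges. The carry-over list stood at -2.44 (5 of 6 lower), led by haemoglobin genes. The mix of clusters within the class was not held fixed. Cluster 10, led by Hp, Lyz2 and Ifitm6, gave 65 of the 158 DFMO and 327 of the 1061 water cells, cluster 6, led by Tgfbi and Ly6i, 65 and 529, and cluster 14, led by C1qa, 28 and 205. In single clusters, added after seeing the data, the neutrophil list stood at 0.98 in cluster 6 (percentile 100) and 0.25 in cluster 10 (percentile 91.3), and the alternative macrophage list at 0.14 and -0.39. The cell cycle list turned to 0.14 in cluster 6, with 6 members measured, and stood at -0.31 in cluster 10 (6 of 6 lower; percentile 1.5). The amino acid stress list stood at -0.17 and -0.20, inside its random ranges. Other lists differed in direction between clusters 6 and 10. The inflammatory macrophage list stood at -0.12 (percentile 12.0) and 0.34 (percentile 99.6). Glycolysis genes stood at 0.21 (percentile 97.9) and -0.27 (percentile 0.03), and immediate early stress genes at -0.17 (percentile 1.4) and 0.28 (percentile 99.98).

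In fibroblast-like cells the highest ratios were those of Stra6 (1.33; 1.03 to 1.62), a retinol transporter gene, Tgtp1 (1.17), an interferon-inducible GTPase gene, Fdps (1.11), a gene of sterol synthesis, Hsd3b7 (1.09), Prune2 (1.06), Ifi211 (1.04), Ass1, Lars2 (1.02) and Traf5 (0.98). Below Hbb-bs (-7.72), of which 1 water cell held 45.6% of the UMIs, the lowest were Ccl8 (-2.83; -3.67 to -2.09), the matrix genes Mfap4 (-2.48), Cilp (-2.05), Bgn (-1.89) and Mfap5 (-1.46), the complement gene C3 (-2.13), and Cryab (-1.76), Id3 (-1.57) and Enpp2 (-1.55). Mfap4 was seen in 2 of 125 DFMO and 107 of 947 water cells. The macrophage genes Apoe, at 1.90 CPM (0.52 to 4.86) and 20.1 CPM (17.6 to 22.9), and C1qb, at 1.90 CPM (0.52 to 4.86) and 9.15 CPM (7.47 to 11.1), were also lower in DFMO in this class. Ccl8 is among the leading genes of the macrophage cluster 14, so carry-over was not separated from its ratio. Some of these ratios followed the mix of cells in the class: subcluster 20 of the finer clustering, led by Mfap4, Postn and Bgn, held 9 DFMO and 165 water cells. Without it, a choice made after seeing the data, Bgn stood at -0.45, Enpp2 at -0.34, Mfap5 at -0.58 and C3 at -1.47, while Ccl8 (-3.08), Cilp (-1.81), Id3 (-1.53) and Ass1 (1.21) moved by less than their intervals. The carry-over list, which holds fibroblast genes, stood at -1.01 (8 of 9 lower), with Hbb-bs and Col1a2 (-4.91) lowest and Pecam1 (0.89) and Col3a1 (-0.03) highest.

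Glycolysis and hypoxia genes in fibroblast-like cells had a median of 0.29 (22 of 23 higher; percentile 100), with Hk2 (0.89) and Gapdh (0.73) highest and Adm (-0.10) and Pfkl (0.05) lowest. Interferon gamma genes stood at 0.22 (16 of 23 higher; percentile 100), from Cxcl9 (0.76) and Iigp1 (0.74) to H2-DMa (-0.36) and H2-DMb1 (-0.28), but at -0.02 as a ratio of summed UMIs. Immediate early stress genes, which tissue dissociation can induce, stood at -0.45 (16 of 17 lower; percentile 0.0), from Hspa1b (0.33) and Hspa8 (-0.10) to Zfp36 (-1.22) and Btg2 (-1.15). The cell cycle list stood at -0.26 (14 of 23 lower; percentile 0.2), from Top2a (0.53) and Rrm2 (0.32) to Cenpe (-1.31) and Ccna2 (-1.28). Respiration genes (-0.02), amino acid stress genes (0.01) and MYC targets (0.02) lay inside their random ranges.

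Ptprc-low cells, the deepest of the large sets with medians of 18599 UMIs per cell in DFMO and 16518 in water, had higher interferon-inducible genes in DFMO. The interferon gamma and antigen presentation list had a median of 0.46 (22 of 23 higher; percentile 100), with H2-Aa (1.67) and H2-Eb1 (1.65) highest and H2-DMb1 (-0.01) and Psmb8 (0.05) lowest, and 0.22 as a ratio of summed UMIs. The highest single ratios after Jchain, whose 604 DFMO UMIs came from 1 cell, were those of H2-Aa, Cd74 (1.45), the chemokine gene Cxcl9 (1.44; 1.31 to 1.56), Tgtp1 (1.24), Hist1h2ap (1.07), Cmpk2 (0.99), AY036118 (0.89), Hopx (0.87) and Rsad2 (0.83), an antiviral gene. H2-Aa was seen in 40 of 545 DFMO cells, and Cd79a stood at 11.7 CPM (9.63 to 14.1) in DFMO and 0.60 CPM (0.36 to 0.94) in water. The 112 DFMO UMIs of Cd79a came from 17 cells, so doublets that were not called were not separated from the MHC class II ratios. The lowest were Ftl1-ps1 (-1.51), Gclm (-1.29), a gene of glutathione synthesis, Gm10073 (-1.20), Eno1b (-0.84), Gm9493 (-0.84), Id3 (-0.77), Fos (-0.66), Ccl7 (-0.66), Lbh (-0.59) and Gadd45g (-0.59). Of the genes named in these sets, Hist1h2ap (93.4%), Eno1b (89.0%), Gm9493 (88.5%), Dynlt1b (86.9%), Gm10282 (83.6%) and Gm10073 (75.8%) had most of their 31-mers in transcripts of other genes, so their UMIs may not be their own.

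Immediate early stress genes in Ptprc-low cells stood at -0.30 (16 of 18 lower; percentile 0.0), from Hspa1b (0.04) and Hspa8 (0.00) to Hspa1a (-1.42) and Fos. Glycolysis genes stood at 0.09 (17 of 23 higher; percentile 99.7), with Hk2 (0.64) and Gapdh (0.51) highest and Adm (-0.24) and Pgam1 (-0.13) lowest, but at -0.01 with each cell weighted alike, and amino acid stress genes at 0.09 (14 of 19 higher; percentile 97.9), with Sesn2 (0.51) and Vldlr (0.48) highest and Atf3 (-0.36) and Chac1 (-0.13) lowest. Cell cycle genes (-0.06), respiration genes (-0.06), MYC targets (0.01) and the carry-over list (0.03) lay inside their random ranges. Gapdh was higher in DFMO in all 5 sets of cells compared, and 27.2% of its 31-mers were shared with transcripts of other genes.

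**Figure D3:**
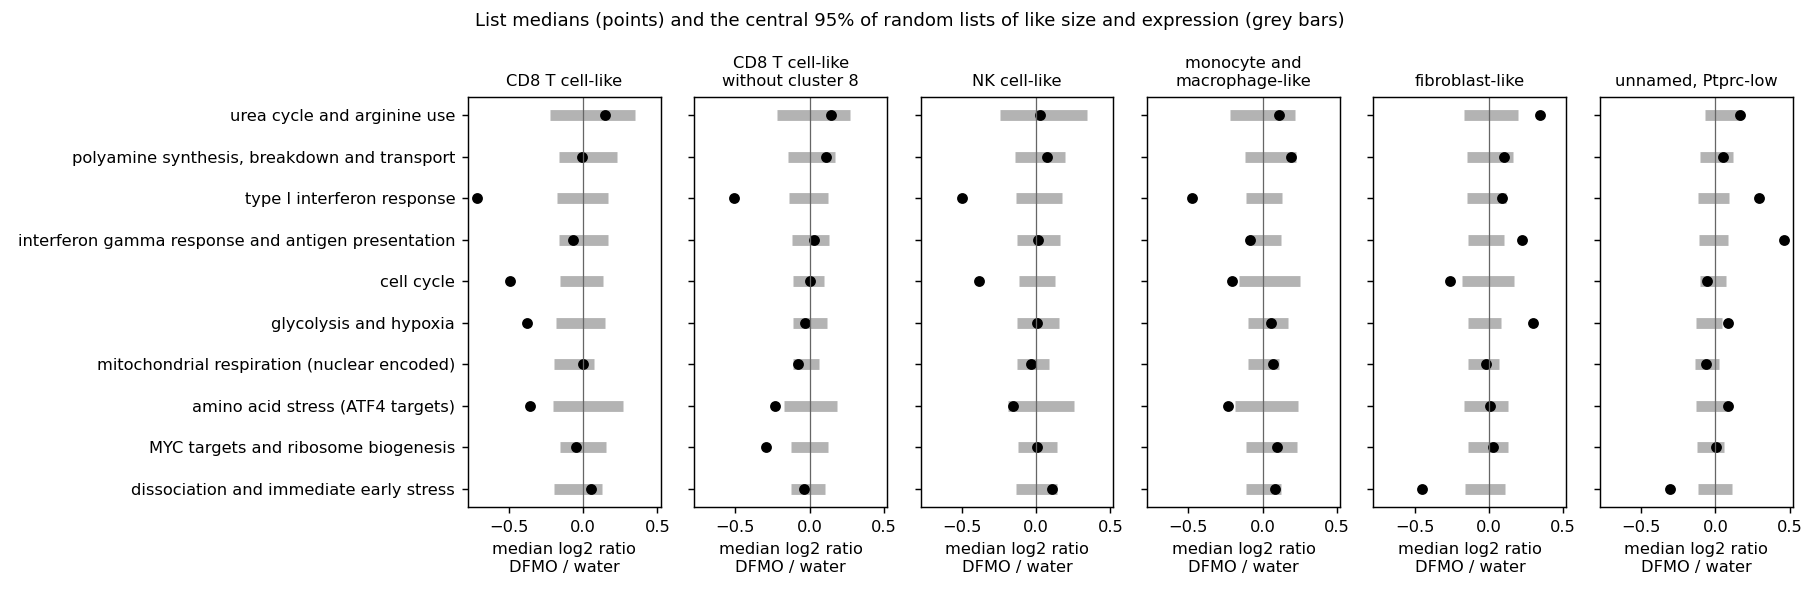
Median log2 ratio of CPM, DFMO over water (x axes), of 10 gene lists (y axis) in 5 cell classes and in CD8 T cell-like cells without cluster 8, as points, with grey bars for the central 95% of random lists of like size and expression. Type I interferon genes lie below the bars in the leukocyte panels (-0.72, -0.51, -0.50 and -0.47) and above it in Ptprc-low cells (0.29).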

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

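The tests without cluster 8, in clusters 6, 7, 9 and 10 alone, without fibroblast-like subcluster 20, with doublets kept but without their cluster 16, and of list medians with each cell weighted alike were chosen after the results were seen, and all other alternatives before. Each group was 1 library, so these values show the effect of processing and not of sampling animals. The planned limits on mitochondrial UMIs could not be run, because the matrix holds no such genes. Of the choices made beforehand, TMM library sizes moved few ratios: 293 of 305 single-gene log2 ratios moved by less than their interval. The same held for 290 with at least 500 genes per cell, 295 with doublets kept, 305 without receptor segments and 219 with each cell weighted alike. TMM moved log2 ratios by -0.02 to -0.09. All 14 shares of cells with a UMI moved when cells were thinned to 1000 UMIs. One cause was tested. With doublets kept, cluster 16 of that clustering, which holds all 187 cells of cluster 15, met the naming rule and joined the monocyte and macrophage-like class. Without it that class was 3.53% of DFMO and 17.1% of water, with Arg1 at 222 and 196 CPM, Odc1 at 39.3 CPM in water and log2 ratios of 0.18 for Arg1, -1.44 for Hspa1b and -1.15 for Ifit3b, all within the main intervals. S100a8 (0.35) stayed outside its interval. The cause of the other changes was not tested, except that dropping or isolating a cluster changes the cells compared.

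Class shares moved as follows. At Leiden resolution 0.5 regulatory T cell-like cells were 4.12% of DFMO and 3.15% of water, the reverse of their order at 1.0, and monocyte and macrophage-like cells 4.28% of DFMO and 19.9% of water. With doublets kept the latter were 4.23% and 19.7%. With at least 500 genes per cell fibroblast-like cells were 2.32% and 14.1%, and Ptprc-low cells 33.4% of water. With each cell weighted alike Odc1 stood at 1208 CPM in water regulatory T cell-like, 130 CPM in DFMO CD8 T cell-like, 134 CPM in water NK cell-like and 30.5 CPM in water monocyte and macrophage-like cells. Arg1 in monocyte and macrophage-like cells was then 158 CPM in DFMO and 175.0 CPM in water, and Ass1 was 108 CPM in DFMO CD8 T cell-like and 283 CPM in DFMO monocyte and macrophage-like cells. With doublets kept the latter class had 43.5 CPM of Odc1 in water, and 373 CPM of Arg1 in DFMO and 489 CPM in water.

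Log2 ratios whose interval excluded 0 changed sign as follows. With each cell weighted alike these were Azin1 in all cells (-0.10), Eif5a in CD8 T cell-like (0.00237) and Mt2 (-0.14) and Gzme (-0.10) in NK cell-like cells. Sat1 in monocyte and macrophage-like cells stood at -0.00043 with TMM, and Gatm in fibroblast-like cells at -0.14 with at least 500 genes. Others kept their sign but moved far when cells were weighted alike over all kept cells: Arg1 (-2.28), Sat2 (-2.40), Gatm (-1.50), Azin2 (-1.42), Pycr1 (-1.41), Smox (-1.32), Col1a1 (-3.41) and Fcer2a (5.39). So did Slc7a2 (-1.67), whose main interval held 0. Ccl3 in NK cell-like cells was then 0.87. The naive list in all cells was 1.64 as a ratio of sums, and the interferon gamma list in Ptprc-low cells 0.22. Of list medians outside their random ranges, those that changed sign with each cell weighted alike were as follows. They were effector (-0.41), exhaustion (-0.29), regulatory T cell (-0.10) and interferon gamma (-0.14) genes in all kept cells and glycolysis genes (-0.01) in Ptprc-low cells. Medians inside their random ranges could also turn, as that of MYC targets in CD8 T cell-like cells did. The urea cycle list (-0.59) and the type I interferon list (-1.23) moved in all kept cells, as did the type I interferon (-1.08), effector (-0.87) and exhaustion (-0.74) lists in CD8 T cell-like cells. Of ratios whose interval held 0, with each cell weighted alike Nos2 turned to -1.13, Odc1 to -0.26, Slc7a1 to -0.21 and Aldh18a1 to -0.19 in all cells, Srm to 0.31 in CD8 T cell-like, Dhps to 0.20 and Oaz1 to 0.05 in Ptprc-low and Arg1 to -0.15 in monocyte and macrophage-like cells. Slc25a13 in fibroblast-like cells turned to -0.30 with at least 500 genes, Arg1 in monocyte and macrophage-like cells to -0.39 with doublets kept, and Odc1 in CD8 T cell-like cells to 0.37 without cluster 8 and 0.49 in cluster 7 alone, where Azin1 turned to -0.22. In CD8 T cell-like cells without cluster 8 those that excluded 0 were Nsg2 (-0.55), Tmem108 (-0.51), Tdrp (-0.13), Tcf7 (-0.042), Lef1 (-0.036) and Ass1 (-0.30), and in cluster 7 alone Tdrp (-0.89), Gzma (1.21) and Ass1 (-0.57). List medians without cluster 8 and in cluster 7 alone were 0.13 and 0.24 for effector molecules, 0.34 and 0.16 for exhaustion genes, 0.41 and 0.31 for naive genes and -0.51 and -0.39 for type I interferon genes. The cell cycle list stood at 0.0 without cluster 8 and -0.26 in cluster 7. In monocyte and macrophage-like cells the urea cycle list stood at 0.41 and the cell cycle list at 0.14 in cluster 6 alone, and the type I interferon list at 0.052 in cluster 10 alone. Without fibroblast-like subcluster 20, 46 of 51 single-gene ratios moved by less than their interval. The carry-over list was 1.94 in CD8 T cell-like and 0.19 in NK cell-like cells with members of at least 100 UMIs (1 member in each), and 0.11 in CD8 T cell-like cells as a ratio of sums. As ratios of sums the interferon lists in fibroblast-like cells were -0.10 (type I) and -0.018 (gamma).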

Other observations

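Tests chosen only after the result was seen were those of NK cell-like against monocyte and macrophage-like cells, of the interferon list in Ptprc-low cells, of the directions of genes that moved alike and of Y-linked genes. The remaining tests were set down before their result was seen, although the value of cluster 7 in the test by cluster had already been looked at. All of them concern patterns found in these data.

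Smaller classes also differed in urea cycle genes. Ass1 in conventional dendritic cell 1-like cells stood at 376 CPM (303 to 461) in 18 DFMO cells and 122 CPM (101 to 145) in 83 water cells. In migratory dendritic cell-like cells it was the other way round, at 526 CPM (437 to 626) and 901 CPM (812 to 996), and also in conventional dendritic cell 2-like cells, at 456 CPM (363 to 566) and 750 CPM (685 to 820). Cluster 15 carried both arginase and nitric oxide synthase transcripts: Nos2 stood there at 210 CPM (148 to 289) in DFMO and 101 CPM (80.7 to 126) in water, beside Arg1 at 1163 and 2197 CPM. Sat1 was highest in endothelial cell-like cells, at 3094 CPM (2557 to 3711) in 5 DFMO cells and 2873 CPM (2522 to 3260) in 16 water cells, and next highest in cluster 15, at 2616 CPM and 2204 CPM.

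B cell-like and CD4 T cell-like cells made up a larger share of the DFMO library. Fewer tumour cells in the DFMO sample would raise every leukocyte class alike. But NK cell-like cells per monocyte and macrophage-like cell, 2 classes outside the pattern, were 3.885 times as many in DFMO (3.04 to 4.98). Fewer tumour cells alone therefore do not account for the class shares, but were not excluded as a part. The B cell-like share was 33.4 times as high in DFMO over all kept cells and 19.3 times among named leukocytes. Lymph node tissue in the DFMO sample may account for naive B and T cells, and its stroma and venule genes had a ratio of 1.24 (0.274 to 4.63) from 4 DFMO and 8 water UMIs of Glycam1, Madcam1 and Prox1. With 3 of the list's 8 genes in the matrix and so few UMIs, this explanation and an effect of DFMO cannot be told apart. The treatment stays open and untested, as there was 1 library per group.

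Type I interferon response genes were lower in DFMO in leukocytes. A difference in scaling or counting between whole libraries would act on all cells, yet the list's median in Ptprc-low cells was 0.29, above the central 95% of random lists (-0.12 to 0.09), by way of cluster 5 (0.51), while clusters 2 (0.16), 3 (0.07) and 12 (0.03) lay inside their own ranges and not below. A different mix of clusters within the classes would leave single clusters inside their random range, yet 6 of 8 leukocyte clusters lay below it, with medians down to -0.51. The exceptions were clusters 10 (0.05) and 11 (-0.09). Of the 6, cluster 13 was a whole class and clusters 0 and 9 were each most of one, so they say little about a mix. Cluster 9 held 184 of the 205 DFMO and 286 of the 354 water NK cell-like cells. In the CD8 T cell-like class cluster 7 (-0.39) lay below and cluster 11 inside. Of the monocyte and macrophage-like clusters, 6 (-0.445) lay below and 10 inside. A mix of these clusters does not account for the values of clusters 6 and 7. It was not excluded as a part of the medians of these 2 classes. A lower interferon response of leukocytes under DFMO may be a biological difference, but other differences between these pools were not tested.

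Some genes moved alike in 5 separate sets of cells. Of 6541 genes measured in all of them, 57 had log2 ratios beyond 0.3 in the same direction in each, where 200 shuffles gave a median of 1 and at most 4, and the limit of 0.3 was set after such genes had been seen. A wrong total of UMIs in one library would move them one way, but 41 were higher and 16 lower. Reads shared with other genes, counted differently in the libraries, are a candidate explanation for part of them: 38.6% had at least 30% of their 31-mers in transcripts of other genes, against 3.5% of the other genes, a ratio of 11.02 (6.77 to 17.1). The others, such as Gclm (median -1.23, 5.6% shared), Cox17 (0.53, 4.8% shared) and Son (0.47, 0.0% shared), stay open, the treatment included.

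Fibroblast-like and Ptprc-low clusters lacked markers of tumour epithelium, and the hypothesis was that they are cells of the implanted line without Y-linked transcripts. Over both libraries the summed CPM of 4 Y-linked genes was 0.95 (0.71 to 1.25) in these clusters, against 148 (143 to 153) in named leukocytes. It was 1.87 (1.21 to 2.76) in fibroblast-like and 0.66 (0.43 to 0.95) in Ptprc-low cells alone. The leukocyte value differed between the libraries, at 197.5 (189 to 206) in DFMO and 106.7 (101 to 112) in water. Endothelial cell-like cells, few in number, stood at 160 (58.7 to 348) in 5 DFMO cells and 35.8 (7.38 to 105) in 16 water cells, or 74.2 (33.9 to 141) together. These values are consistent with most of these clusters being cells of the line, though the list cannot say so of each cell.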
